A study of Mus musculus with 12 samples.

How the data were processed

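Total RNA of sorted bone marrow CMP and LSK cells was extracted with a carrier, amplified with a kit for very small amounts of RNA, and sequenced as paired reads of 75 bp, per the labels' protocols. The deposited values are raw counts of reads per gene symbol, 1 file per library. Per the submitters' processing notes, TopHat2 2.0.4, TopHat, Bowtie and HTSeq were used with the mm10 build. The annotation, the counting mode and the strand setting are not given in the sources used here. The kit chain does not mark strand as far as the labels tell, so genes that overlap on opposite strands, and close paralogs, cannot be told apart with certainty. Rows that name no gene (no feature, ambiguous, not unique) held 37.2% to 46.9% of the counts per library and were left out of library sizes and tests.

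The 12 files did not list the same genes. The file of wild-type CMP replicate 6 listed 23456 symbols and the other 11 files 24420. That file may have been counted with another annotation, so a shared symbol may cover different exons there, which identical symbols alone cannot show. The authors' deposited counts were joined on 22779 identical symbols and 604 symbols that the RefSeq gene table (assembly GRCm38.p6) links one to one as older names, 23383 genes in all. Between 0.075% and 0.303% of the gene counts of a library were not joined. Positions were taken from a GENCODE annotation of the same build.

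Replicates of a group were compared first. No 2 files held identical values, and chi-square per degree of freedom between replicates of a group was 44.3 to 192, so that each library entered as 1 replicate. All 12 libraries carried the name of the same sequencing run, and no batch was found in the labels. Total gene counts ran from 6170491 to 49149674. The floor of 3 counts corresponds to 0.0612 to 0.487 CPM, and intervals cover counting error only, because the amplified reads carry no molecular identifiers. The labels do not say that replicates of a group came from separate animals. P-values therefore measure the spread between these libraries.

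Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, robust, TMM scaling, default expression filter with a minimum count of 10) and Benjamini-Hochberg adjustment at 0.05, on the libraries of the groups compared. The standard error of a log2 fold change was taken as its size divided by the root of the F statistic. The biological coefficient of variation was 0.719 to 0.823. Levels were CPM scaled by TMM over the 12 libraries. The median log2 fold change of all genes lay between −0.0218 and 0.0112.

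For each of 26 gene lists with at least 3 tested members, camera of limma 3.58.1 was run with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. The same test with an estimated correlation, and fry, were alternatives. Of the 44 calls with the preset correlation in the genotype, interaction and wild-type comparisons, only the stem cell list in the wild-type cell type comparison held with an estimated correlation. For each of the 44 the adjusted p with an estimated correlation was the highest among its alternatives. In the genotype and cell type comparisons a list's median did not move when members with 0 counts in a whole group were set to their bound, a floor of 3 counts over the group.

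Named genes followed a rule fixed before the data were examined. For each genotype comparison it took the CEBP family members, the 10 largest rises and 10 largest falls past the threshold, and up to 4 members of each list past the threshold or else the member with the smallest p. The largest changes were limited to genes with a mean of at least 5 CPM in the higher group, no overlap between the libraries of the 2 groups, and a gene name. The interaction took 5 each way, and the wild-type cell type comparison 8 each way and up to 3 members of each list. Named outside this rule, after their values were seen, were the list members given for the interaction, the genes given as levels in the enhancer-null cell type comparison, and the marker genes of other cell types given by library. Elane in LSK was also named outside this rule, after its values were seen. Some genes that these choices took are not reported here.

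The pipeline was tested on simulated counts with 200 changed genes. For the genotype effect in CMP (11722 genes), edgeR recovered 2% of changes of 1 on the log2 scale, 32% of 2, 60% of 3 and 62% of 4, with 1.27% false calls, and DESeq2 recovered more with 28.6% false calls. For LSK (11619 genes), edgeR recovered 10%, 36%, 62% and 48% for the same sizes, with 4.88% false calls. A simulated list of 20 genes shifted by 1 was called with the preset correlation in all 5 comparisons (adjusted p up to 1.51e-05). With an estimated correlation it was called in CMP (adjusted p = 0.0227) and missed in LSK (0.143), the interaction (0.105) and the wild-type (0.135) and enhancer-null (0.103) cell type comparisons. Simulated genes were drawn independently, so these runs could not show how the preset test behaves when members of a list vary together. Each gene was given the spread of the fitted trend at its level rather than its own. The shares of false calls therefore need not hold for the real libraries.

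Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of 1 CPM in every library of a group, no robust prior, a fit on all 12 libraries, the replicate number as a block, and each library left out. Alternatives chosen after seeing the data were sex as a covariate, thinning of all libraries to 6157633 gene counts, identical symbols alone, all symbols of the LSK files, and the interaction without the 2 libraries with most zeros. The CMP and LSK libraries share replicate numbers within a genotype, whereas the enhancer-null and wild-type groups share only number 1, so genotype comparisons were not paired.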

Results

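RNA was sequenced from sorted bone marrow progenitors of C57BL/6 mice, which either lacked both copies of an enhancer 42 kb downstream of Cebpa or were wild type. Cebpa encodes a transcription factor of granulocyte and monocyte commitment. Common myeloid progenitors (CMP) and the LSK fraction were collected from each genotype, giving 4 groups of 3 libraries. LSK is the lineage-negative, Sca-1-positive, Kit-positive population that contains the stem cells. The libraries are named by group and by the number in their label, which was 1, 2 or 7 in the enhancer-null and 1, 6 or 8 in the wild-type groups. Counts assigned to genes totalled 8976999 to 20122669 per library in enhancer-null CMP and 15470260 to 32770938 in wild-type CMP. They totalled 6170491 to 49149674 in enhancer-null LSK and 14753266 to 34080293 in wild-type LSK. Levels are given as CPM, counts scaled to library size. Among genes with a mean of at least 10 CPM, 3.58% had no count in enhancer-null CMP replicate 1 and 1.82% had none in wild-type LSK replicate 6. Xist and the Y-linked genes marked enhancer-null replicates 1 and 2 and wild-type replicate 1 as male and the other numbers as female, in CMP and LSK alike, so that sex was not balanced between the genotypes. CPM were scaled over the 12 libraries and are given as mean ± SD with n = 3. P-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

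The targeted gene was examined first in every library. Cebpa (ENSMUSG00000034957.10, a protein-coding gene on the plus strand of chromosome 7, 35119293 to 35121928, build mm10) was counted 544, 270 and 463 times in wild-type CMP, a level of 20.9 ± 8.4 CPM. The 3 enhancer-null CMP libraries held 0, 3 and 0 counts. The ratio of summed, depth-scaled counts was 295 in favour of the wild type, with a 95% counting interval of 101 to 1430. In LSK the counts were 226, 118 and 39 in the wild type (5.71 ± 2.98 CPM) and 1, 0 and 15 in enhancer-null animals (0.125 ± 0.155 CPM). No enhancer-null library reached the lowest wild-type value in the same cell type. The difference did not pass edgeR's test in CMP (adjusted p = 0.0817) or in LSK (log2 fold change −5.24, SE 1.77, adjusted p = 0.499). Over 15 alternatives the adjusted p ran from 5.8e-08 to 0.338 in CMP, where 3 passed, and from 0.0489 to 0.951 in LSK, where 1 passed. The lowest value was that of DESeq2 in both. Adjusted over the list alone, Cebpa was lower (adjusted p = 0.00693) and Cebpb, another family member, higher in CMP (adjusted p = 0.0276). Cebpb stood at 265 ± 169 CPM in enhancer-null and 87 ± 24.7 in wild-type CMP (adjusted p = 0.212), and Cebpd and Cebpg at adjusted p of 0.412 and 0.571. Cebpe, a regulator of late granulopoiesis, was at 0.197 ± 0.341 against 1.46 ± 1.32 CPM in CMP (adjusted p = 0.687) and was too low to be tested in LSK. In LSK the adjusted p was 0.696 for Cebpb, 0.902 for Cebpd and 0.84 for Cebpg.

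**Figure D1:**
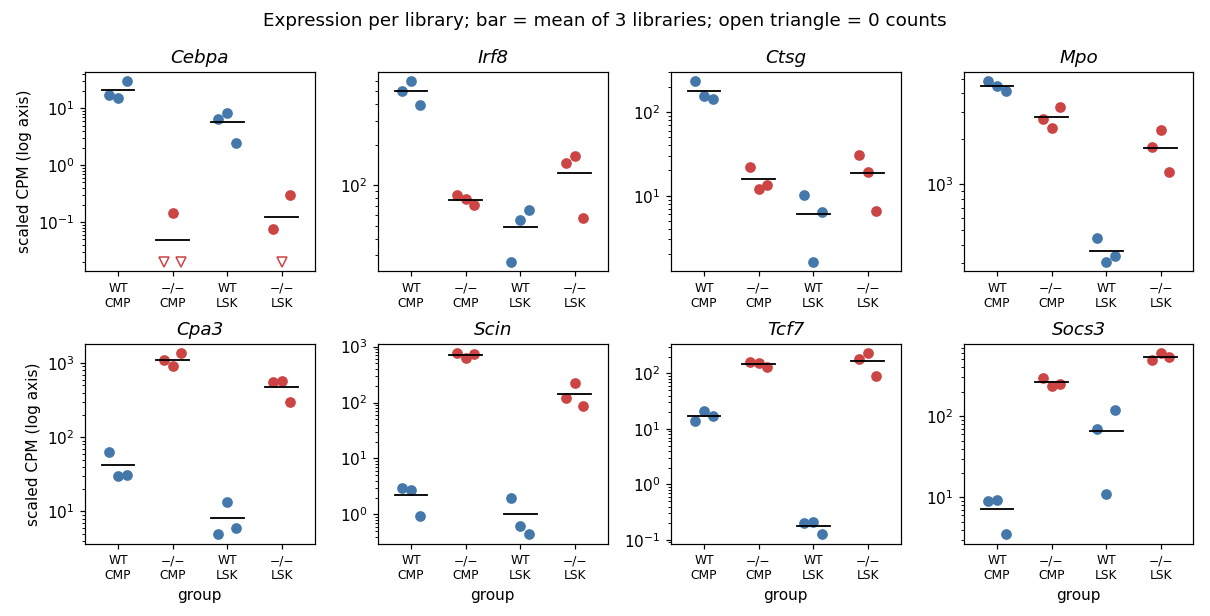
Scaled CPM (vertical log axis) of 8 genes in each of the 12 libraries, by group (horizontal axis); each point is a library, the bar is the mean of 3 libraries and an open triangle marks 0 counts. Cebpa lies at 0 to 0.298 CPM in the enhancer-null libraries, and Scin averages 708 CPM in enhancer-null and 2.19 CPM in wild-type CMP.

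The comparison of enhancer-null with wild-type CMP asked which genes differed in the gate where granulocyte and monocyte fates are entered. As lists, monocyte genes were lower (2 of 15 past the test) and mast cell and basophil genes higher (3 of 12) in the enhancer-null cells, with adjusted p = 3.78e-10 and 1.85e-13, and adjusted p = 0.132 for each with an estimated correlation. Of the 12 mast cell and basophil genes, 4 had a negative log2 fold change. F13a1, coagulation factor XIII A of monocytes, fell from 477 ± 88.8 to 1.29 ± 1.84 CPM (log2 fold change −8.39, SE 1.11, adjusted p = 0.0261). Irf8, the transcription factor of monocyte and dendritic cell commitment, fell from 498 ± 101 to 78 ± 6.7 CPM (log2 fold change −2.68, SE 0.21, adjusted p = 0.00424). Cpa3, the carboxypeptidase of mast cell granules, rose from 41.7 ± 19.5 to 1117 ± 222 CPM (log2 fold change 4.74, SE 0.37, adjusted p = 0.00424). Scin, an actin-severing protein, rose from 2.19 ± 1.1 to 708 ± 62.9 CPM (log2 fold change 8.29, SE 0.45, adjusted p = 0.0016).

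Of 11722 genes tested in CMP, 56 rose and 13 fell. The largest rises beside Scin and Cpa3 were those of Gzmb (granzyme B, a protease of cytotoxic granules, from 0.801 ± 1.01 to 468 ± 190.3 CPM), Socs3 (a feedback inhibitor of cytokine signalling, 7.29 ± 3.29 to 262 ± 33), Clec4e, Ffar2, Ifitm1 (36.7 ± 2.92 to 556 ± 137), Siglecf, Zbtb16 and Mycn. The log2 fold change was 3.57 for Mycn (adjusted p = 0.0452), the smallest of these, and the fold change was 511 for Gzmb (adjusted p = 0.0121), the largest. The largest falls beside F13a1 and Irf8 were those of Tmem243, Anxa3, Ms4a6c, Dtx4, Ctsg (cathepsin G), Emb, Tifab and Unc93b1. Tmem243 was left with 3 counts in the enhancer-null group, a ratio of 337 (95% counting interval 115 to 1640), and Unc93b1 fell by 2.43 on the log2 scale.

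Among 15 tested monocyte and macrophage genes, F13a1 and Ms4a6c fell and 13 did not pass the test, with 7 lower when adjusted over the list alone. The list as a whole fell (median log2 fold change −4.12, camera adjusted p = 3.78e-10), and its adjusted p = 0.132 with an estimated correlation. Of 15 primary granule genes, Ctsg fell from 177 ± 50.7 to 15.8 ± 5.59 CPM and Clec12a, a lectin of myeloid cells, from 187 ± 28.4 to 49.1 ± 14.9, and 13 did not pass. Adjusted over the list alone, 7 were lower and 1 higher. The list fell (median −0.69, adjusted p = 2.58e-05, and adjusted p = 0.269 with an estimated correlation). Late neutrophil transcripts were unevenly spread over the wild-type libraries: S100a8 stood at 388, 30.8 and 8.7 CPM in wild-type CMP replicates 1, 6 and 8 and at no more than 6.01 CPM in enhancer-null CMP. The late neutrophil list did not pass in CMP (14 genes tested, 11 negative and 3 positive, median −5.59, adjusted p = 0.0782, and adjusted p = 0.611 with an estimated correlation), but passed as lower in 4 of 6 fits that left out 1 library and with sex as a covariate. Its adjusted p was 0.394 without wild-type replicate 1, and 2 members were higher and 5 lower adjusted over the list alone. Within the granulocyte and monocyte regulators, Irf8 fell while Sox4 (389 ± 76.8 to 1197 ± 251 CPM) and Id2 (16 ± 3.56 to 141 ± 78.2) rose. Adjusted over the list alone, 4 were higher and 3 lower, and the list itself did not pass (adjusted p = 0.205).

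Of 12 tested mast cell and basophil genes, Cpa3, Gzmb and Ifitm1 rose and 9 did not pass, with 7 higher and 1 lower adjusted over the list alone. Of the 12 log2 fold changes, 8 were positive and 4 negative. The list rose (median log2 fold change 2.63, adjusted p = 1.85e-13, and adjusted p = 0.132 with an estimated correlation). Gzmb is a protease of cytotoxic granules, and Ifitm1 is a broadly expressed membrane protein that is also in the stem cell list. Siglecf, an eosinophil lectin, rose from 8.19 ± 2.01 to 109 ± 45.1 CPM, and fewer than 3 eosinophil genes could be tested. Tcf7, a transcription factor of T cell and stem cell programmes, rose from 17.3 ± 3.41 to 150 ± 16.7 CPM, as did Lat from 12.2 ± 0.594 to 81.4 ± 24. They were the 2 of 12 T and NK cell genes to pass, with 5 higher and 1 lower adjusted over the list alone (median 2.44, list adjusted p = 4.13e-05, and adjusted p = 0.132 with an estimated correlation). Cd79a, a marker of B cells, was highest in wild-type CMP replicate 1, at 21 CPM. The basophil protease Prss34 was at 112 CPM in the same library and at no more than 0.391 CPM in the other CMP libraries.

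Immediate early genes rose as a list in CMP (median log2 fold change 0.84, adjusted p = 1.9e-11, and adjusted p = 0.234 with an estimated correlation). Ier3, Junb, Ier2 and Jund rose, with Ier3 going from 42.1 ± 8.36 to 388 ± 49 CPM, and 21 of 25 members did not pass. Adjusted over the list alone, 9 were higher and 1 lower. Socs3 and Pim1 were the 2 of 29 inflammatory signalling genes to rise, with 6 higher adjusted over the list alone (median 0.79, list adjusted p = 0.000143, and adjusted p = 0.234 with an estimated correlation). Of 36 stem cell genes, Ifitm1 and Angpt1 (82.1 ± 26.2 to 553 ± 214 CPM) rose, with 9 higher and 3 lower adjusted over the list alone (list adjusted p = 0.00518, and adjusted p = 0.132 with an estimated correlation). The stem cell list was called higher although 19 log2 fold changes were positive and 17 negative (median 0.17). Nfe2, a platelet and erythroid transcription factor, was the only one of 20 megakaryocyte genes to rise, with 6 higher adjusted over the list alone (list adjusted p = 0.00103, and adjusted p = 0.132 with an estimated correlation). The list's adjusted p was 0.0661 without wild-type replicate 8.

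No single G2 and mitosis gene passed the test in CMP, but the list fell (32 genes, 31 with a negative and 1 with a positive log2 fold change, median −0.86, adjusted p = 8.04e-12, and adjusted p = 0.234 with an estimated correlation), with 9 lower adjusted over the list alone. Cdk1 stood at 94.3 ± 11.4 against 191 ± 11.9 CPM (adjusted p = 0.0795). The list of 37 DNA replication genes fell (median −0.64, adjusted p = 2.95e-07, and adjusted p = 0.191 with an estimated correlation). So did those of 80 respiratory chain genes (median −0.33, adjusted p = 5.06e-06, and adjusted p = 0.426 with an estimated correlation) and 80 ribosomal protein genes (median −0.20, adjusted p = 0.000778, and adjusted p = 0.611 with an estimated correlation). These 3 lists had 0 members past the test, over all genes or adjusted over the list alone. The same held for 23 unfolded protein and amino acid stress genes (median −0.37, adjusted p = 0.00517, and adjusted p = 0.234 with an estimated correlation) and 34 erythroid genes (median −0.31, adjusted p = 0.023, and adjusted p = 0.611 with an estimated correlation). Single libraries ended 3 of these calls. The ribosomal list was at adjusted p = 0.374 without enhancer-null replicate 2 and 0.0875 without wild-type replicate 1, and the stress list at 0.133 without enhancer-null replicate 2. The erythroid list was at 0.296 without enhancer-null replicate 1, 0.439 without enhancer-null replicate 7 and 0.154 without wild-type replicate 8. Interferon response, dendritic cell, lymphoid, B cell, p53 target, cholesterol, stromal, sex-linked and CEBP family lists did not pass (adjusted p from 0.0731 to 0.801), although Usp18 and Id2, members of the first and the second, rose. Adjusted over the list alone, 1 dendritic cell gene was higher and 2 lower, and 2 lymphoid genes were higher and 2 lower. Likewise 3 p53 targets were higher and 1 lower, 1 interferon gene higher and 1 lower, and 1 stromal gene higher, with 0 B cell, cholesterol and sex-linked genes past the test. The interferon and stromal lists were tested as higher although their mean log2 fold changes were −0.20 and −0.42.

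The count of 69 genes in CMP rested on all 3 wild-type libraries: it was 13 without wild-type replicate 1, 7 without replicate 6, 7 without replicate 8 and 43 without enhancer-null replicate 7. Among the named genes Ier3, Ifitm1, Irf8, Scin and Socs3 passed in all 6 fits that left out 1 library. Cpa3 was lost without wild-type replicate 8, and F13a1 without any one of the 3 wild-type libraries (adjusted p up to 0.0527 for Cpa3 and 0.169 for F13a1 over 15 alternatives). DESeq2 called 629 genes, of which 64.4% rose against 81.2% in edgeR, and sex as a covariate gave 31.

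**Figure D2:**
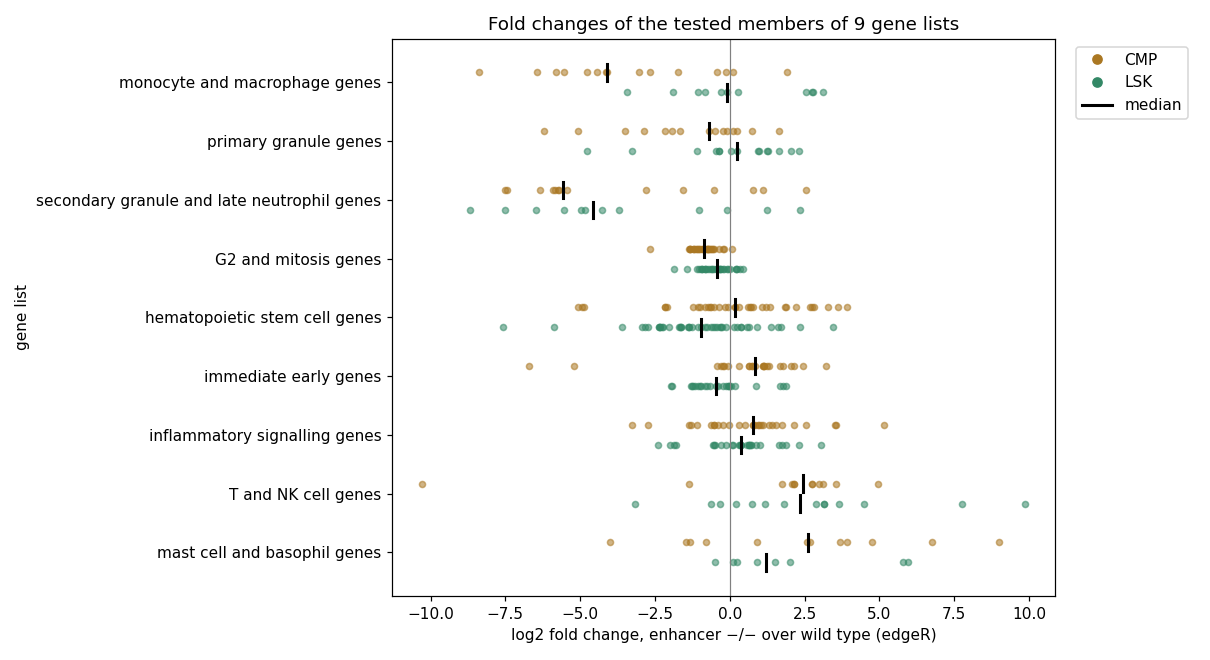
Log2 fold change of enhancer-null over wild-type cells (horizontal axis, edgeR) for each tested member of 9 gene lists (vertical axis), in CMP and in LSK; each point is a gene and the black bar is the list's median. The mast cell and basophil medians lie at 2.63 in CMP and 1.21 in LSK, and the stem cell median at −0.96 in LSK.

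The comparison of enhancer-null with wild-type LSK asked whether the stem and progenitor fraction upstream of CMP also differed. As lists, mast cell and basophil genes were higher (1 of 8 past the test) and stem cell genes lower (1 of 45 lower and 1 higher), with adjusted p = 2.31e-07 and 4.29e-08, and adjusted p = 0.17 and 0.131 with an estimated correlation. Mpo, the myeloperoxidase of primary granules, rose from 362 ± 71.2 to 1751 ± 543 CPM (log2 fold change 2.31, SE 0.26, adjusted p = 0.0396). Cpa3 rose from 8.03 ± 4.55 to 476 ± 155 CPM (log2 fold change 5.94, SE 0.50, adjusted p = 0.0128), and Tcf7 from 0.178 ± 0.0462 to 169 ± 70.8 CPM (log2 fold change 9.85, SE 0.56, adjusted p = 0.00299). Lmo2, a transcriptional adaptor needed for stem cell formation, fell from 1076 ± 14.9 to 350.4 ± 55.7 CPM (log2 fold change −1.59, SE 0.13, adjusted p = 0.0128).

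Of 11619 genes tested in LSK, 9 rose and 3 fell. The other rises were those of Scin (1.01 ± 0.829 to 142 ± 70.6 CPM), Ctr9, Itga2b (the platelet integrin CD41, 31.6 ± 1.44 to 122 ± 5.81), Ier3, Adgrg3 and Cd48 (113 ± 12 to 283 ± 10.1), a surface protein that is low on the most primitive stem cells. Hk3, a hexokinase of myeloid cells, fell from 96.5 ± 8.99 to 16.5 ± 3.24 CPM. Cpa3, Ier3, Scin and Tcf7 rose in both cell types, where 0.0453 shared rises were the expectation for independent lists (Fisher's exact test, one-sided, p = 7.09e-08). Of the 13 falls in CMP and 3 in LSK 0 were shared, where 0.0035 were the expectation. That 0 could therefore not tell shared falls from separate ones. With DESeq2, 56 genes rose in both (expectation 4.72) and 17 fell in both, Cebpa among them (expectation 1.89). The CMP and LSK libraries carry the same replicate numbers and sexes, so the 2 comparisons may not be independent.

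The stem cell list fell in LSK (45 genes, median log2 fold change −0.96, adjusted p = 4.29e-08, and adjusted p = 0.131 with an estimated correlation). Cd48, a list member whose known expression runs the other way, rose. Adjusted over the list alone, 12 were lower and 4 higher. Hoxa9, a self-renewal regulator, stood at 81.3 ± 25.7 against 255 ± 18.2 CPM (adjusted p = 0.113). Of 8 mast cell and basophil genes Cpa3 rose and 7 did not pass, with 3 higher adjusted over the list alone (median 1.21, list adjusted p = 2.31e-07, and adjusted p = 0.17 with an estimated correlation). Tcf7 was the 1 of 14 T and NK cell genes to rise, with 3 higher adjusted over the list alone (median 2.36, list adjusted p = 2.87e-09, and adjusted p = 0.131 with an estimated correlation). Mpo was the 1 of 15 primary granule genes to rise, while 9 had a positive and 6 a negative log2 fold change, with 5 higher and 1 lower adjusted over the list alone (median 0.24, list adjusted p = 0.00222, and adjusted p = 0.403 with an estimated correlation). Elane, another member, went the other way without passing the test over all genes. It stood at 0.304, 11.5 and 0.0198 CPM in enhancer-null LSK replicates 1, 2 and 7. In wild-type LSK replicates 1, 6 and 8 it stood at 84.8, 17.3 and 11.7 CPM.

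The late neutrophil list fell in LSK with 0 of 12 members past the test over all genes, and with 5 lower and 1 higher adjusted over the list alone (median −4.57, list adjusted p = 1.32e-06, and adjusted p = 0.236 with an estimated correlation). Camp, an antimicrobial peptide of secondary granules, stood at 0.292 ± 0.117 against 59.1 ± 73.5 CPM (adjusted p = 0.113), and its wild-type level came to 144 CPM in replicate 1, 20.9 in replicate 6 and 12.7 in replicate 8. A further 6 lists passed with 0 members past the test over all genes. Ribosomal protein genes fell (80 genes, median −0.20, adjusted p = 1.64e-06, and adjusted p = 0.644 with an estimated correlation), as did G2 and mitosis genes (median −0.43, adjusted p = 0.00125, and adjusted p = 0.572 with an estimated correlation). Interferon response genes fell (47 genes, median −0.34, adjusted p = 0.00178, and adjusted p = 0.403 with an estimated correlation), and none of these 3 lists had a member past the test adjusted over the list alone. The G2 list was at adjusted p = 0.0614 without wild-type replicate 1 and the interferon list at 0.0808 without wild-type replicate 6. Stromal genes rose (7 genes, median 1.49, 1 higher adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.418 with an estimated correlation), with adjusted p = 0.228 without enhancer-null replicate 1 and 0.0876 without replicate 7. B cell genes fell (5 genes, median −0.88, 1 lower adjusted over the list alone, adjusted p = 0.0204, and adjusted p = 0.236 with an estimated correlation). That list was at adjusted p = 0.152 without enhancer-null replicate 1, 0.0501 without enhancer-null replicate 7 and 0.0556 without wild-type replicate 6. Inflammatory signalling genes rose (28 genes, 6 higher and 2 lower adjusted over the list alone, median 0.37, adjusted p = 0.0155, and adjusted p = 0.236 with an estimated correlation). The other 14 tested lists did not pass (adjusted p from 0.0811 to 0.855), although Ier3 of the immediate early and Itga2b of the megakaryocyte list rose. The monocyte and megakaryocyte lists were tested as higher although the median of the former was −0.11 and the mean of the latter −0.28. The dendritic cell and stress lists were tested as lower although the mean of the former was 0.45 and the median of the latter 0.05.

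The 12 calls in LSK rested on single libraries: 1 gene passed without enhancer-null replicate 1, without enhancer-null replicate 2 or without wild-type replicate 8. The count was 2 without wild-type replicate 1, 6 without enhancer-null replicate 7, 21 without wild-type replicate 6, 268 with DESeq2 (50% higher, against 75% in edgeR) and 3 with sex as a covariate. Tcf7 was the 1 named gene that passed in all 6 fits that left out 1 library. Mpo, Cpa3 and Lmo2 were each lost without enhancer-null replicate 1, enhancer-null replicate 2, wild-type replicate 1 or wild-type replicate 8, Mpo also without wild-type replicate 6. Their adjusted p reached 0.255, 0.135 and 0.145 over 15 alternatives.

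The interaction test asked which genotype effects differed between CMP and LSK. As lists, monocyte (1 of 19 past the test) and primary granule genes (2 of 15) had a more negative genotype effect in CMP than in LSK (adjusted p = 1.78e-07 and 2.3e-10, and adjusted p = 0.102 and 0.0664 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, stood at 17 ± 10.5 against 139 ± 39.5 CPM in CMP and at 47.5 ± 29.6 against 7.05 ± 2.74 CPM in LSK, a log2 difference of −5.77 (SE 0.89, adjusted p = 0.0183). By edgeR's test within each cell type, the genotype effect of Csf1r passed neither in CMP nor in LSK (adjusted p = 0.253 in LSK). Irf8 differed by −4.00 (SE 0.55, adjusted p = 0.00882) and Ctsg by −5.10 (adjusted p = 0.0458). Tcf7 rose in both cell types but less in CMP, whose wild-type level was already higher (difference −6.70, SE 0.55, adjusted p = 0.000218). The size of that difference rests on a wild-type LSK level near the floor. Cd63, a granule and lysosome membrane protein, stood at 338 ± 81 against 33 ± 14.7 CPM in CMP and at 165 ± 17.8 against 210 ± 41.7 CPM in LSK (difference 3.70, SE 0.42, adjusted p = 0.00203).

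Of 12684 genes, 28 had a more positive genotype effect in CMP than in LSK and 9 a more negative one. Beside Cd63, the largest positive differences were those of Ctla2b (4.20), Lax1 (3.85), Slc18a2 (3.46) and Ltb (3.41), and the largest negative ones were those of Tcf7, Csf1r, Ctsg, Irf8 and Atp8b4 (−3.43). The difference was negative for primary granule genes (15 tested, Mpo and Ctsg past the test, 6 adjusted over the list alone, adjusted p = 2.3e-10, and adjusted p = 0.0664 with an estimated correlation). It was negative for monocyte and macrophage genes (19 tested, Csf1r past the test, 2 adjusted over the list alone, adjusted p = 1.78e-07, and adjusted p = 0.102 with an estimated correlation). It was also negative for the granulocyte and monocyte regulators (28 tested, Irf8 and Csf1r past the test, adjusted over the list alone 3 lower and 1 higher, adjusted p = 0.00261, and adjusted p = 0.0664 with an estimated correlation). It was positive for immediate early genes (26 tested, Ier3, Junb and Egr1 past the test, 10 adjusted over the list alone, adjusted p = 1.63e-13, and adjusted p = 0.186 with an estimated correlation). It was positive for stem cell genes (45 tested, Ifitm1, Angpt1, Gata2 and Gimap1 past the test, 7 higher and 3 lower adjusted over the list alone, adjusted p = 3.05e-05, and adjusted p = 0.0664 with an estimated correlation). The mast cell and basophil list was also called positive, although 6 of its 12 differences were positive and 6 negative (median 0.31, Ifitm1 and Gata2 past the test, 4 adjusted over the list alone, adjusted p = 0.00209, and adjusted p = 0.25 with an estimated correlation), at adjusted p = 0.089 without wild-type CMP replicate 8. DNA replication (adjusted p = 0.0266, and adjusted p = 0.573 with an estimated correlation) and respiratory chain genes (adjusted p = 0.0399, and adjusted p = 0.689 with an estimated correlation) had a negative difference with 0 members past the test over all genes, and 0 and 1 adjusted over the list alone. The replication list was at adjusted p = 0.0652 and 0.139 without enhancer-null LSK replicate 2 or 7 and at 0.0632 and 0.0591 without wild-type LSK replicate 1 or 6. The respiratory chain list was at 0.0881 without enhancer-null CMP replicate 2, 0.184 without wild-type CMP replicate 1, 0.0603 and 0.0652 without enhancer-null LSK replicate 1 or 2, and 0.207 without wild-type LSK replicate 1. The remaining 18 lists did not pass (adjusted p from 0.0607 to 0.917), although Nfe2, Lax1 and Lat had a positive and Tcf7 and Pdia4 a negative difference. The late neutrophil and p53 lists were tested as positive although their mean differences were −0.47 and −0.34.

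The count of 37 was 107 without enhancer-null CMP replicate 2, with 42 differences positive and 65 negative, and 17 without replicate 1, and 20, 12 and 18 without wild-type CMP replicate 1, 6 or 8. It was 18, 16 and 19 without enhancer-null LSK replicate 1, 2 or 7, 19 without wild-type LSK replicate 8, and 186 with DESeq2. Cd63, Irf8 and Tcf7 passed in all 12 fits that left out 1 library, and over 21 alternatives their adjusted p reached 0.0253, 0.0599 and 0.00676. Csf1r was lost without wild-type CMP replicate 6 or 8 or wild-type LSK replicate 8 (adjusted p up to 0.193 over the 21), and Ctsg in 9 of the 12 (up to 0.144). Lax1, Ltb and Atp8b4 were each lost in 11 of the 12, Slc18a2 in 8 and Ctla2b in 1 (adjusted p up to 0.172, 0.189, 0.146, 0.165 and 0.0912 over the 21).

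The comparison of CMP with LSK in wild-type animals described the step between the 2 gates. As lists, stem cell genes were lower in CMP (17 of 43 lower and 1 higher past the test), and erythroid (19 of 34), primary granule (5 of 15 higher and 1 lower), G2 and mitosis (8 of 32) and DNA replication genes (9 of 37) higher. With an estimated correlation the stem cell list passed (adjusted p = 0.00569) and the other 4 did not (adjusted p = 0.0694, 0.233, 0.152 and 0.0866). Hlf, a stem cell transcription factor, fell from 435 ± 47.7 CPM in LSK to 12.6 ± 0.683 in CMP (log2 fold change −5.07, SE 0.19, adjusted p = 8.41e-05). Ly6a, which encodes the Sca-1 antigen used for the LSK gate, fell from 152 ± 20.7 to 4.82 ± 1.32 CPM. Mpo rose from 362 ± 71.2 to 4478 ± 357 CPM (log2 fold change 3.67, SE 0.16, adjusted p = 0.000205), and Ermap, an erythrocyte membrane protein, from 1.59 ± 1.57 to 300.5 ± 71.8 CPM (log2 fold change 7.49, SE 0.80, adjusted p = 0.00657).

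Of 12027 genes, 258 were higher and 247 lower in wild-type CMP. The largest rises by the naming rule were those of Tmem119, Plxdc1, Ccdc68, Spon2, Cx3cr1 (the fractalkine receptor of monocytes, 0.0663 ± 0.115 to 23.5 ± 6.21 CPM), Pklr (pyruvate kinase of red cells, 0.132 ± 0.128 to 38.4 ± 10.9), Dapk2 and Sowaha. The largest falls were those of Wfdc2, which had 0 counts in CMP and was at least 196-fold lower, Upp1, Fam181b, Ndn, Col16a1, Mmp2, Trib3 and Nkx2-3 (119 ± 17.7 to 2.99 ± 1.52 CPM). Of 43 stem cell genes 17 fell and 1 rose, with 30 lower and 2 higher adjusted over the list alone (median log2 fold change −2.60, adjusted p = 1.58e-32, and adjusted p = 0.00569 with an estimated correlation). Of 34 erythroid genes 19 rose, among them Blvrb, with 28 higher and 2 lower adjusted over the list alone (median 4.35, adjusted p = 1.2e-31, and adjusted p = 0.0694 with an estimated correlation).

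Of 24 immediate early genes 11 fell, among them Nr4a1 (518 ± 161 to 51.4 ± 2.51 CPM), with 15 lower adjusted over the list alone (list adjusted p = 1.1e-20, and adjusted p = 0.165 with an estimated correlation). Of 32 G2 and mitosis genes 8 rose, including Mki67 (337 ± 59.8 to 697 ± 53.1 CPM), with 15 higher adjusted over the list alone (list adjusted p = 5.09e-15, and adjusted p = 0.152 with an estimated correlation). DNA replication genes rose (9 of 37, 16 adjusted over the list alone, list adjusted p = 3.45e-12, and adjusted p = 0.0866 with an estimated correlation). Interferon response genes fell (6 of 47, 18 adjusted over the list alone, list adjusted p = 1.74e-14, and adjusted p = 0.0866 with an estimated correlation). Primary granule genes rose (5 of 15 higher and 1 lower, 6 and 1 when adjusted over the list alone, list adjusted p = 5.55e-08, and adjusted p = 0.233 with an estimated correlation). Monocyte and macrophage genes rose (5 of 16, 6 adjusted over the list alone, list adjusted p = 3.46e-07, and adjusted p = 0.141 with an estimated correlation). Respiratory chain genes rose (9 of 80, 24 adjusted over the list alone, list adjusted p = 3.88e-10, and adjusted p = 0.353 with an estimated correlation). Inflammatory signalling genes fell (4 of 29, 11 lower and 1 higher adjusted over the list alone, list adjusted p = 1.72e-05, and adjusted p = 0.0866 with an estimated correlation). Unfolded protein and amino acid stress genes rose as a list (2 higher and 2 lower of 25, 7 and 2 adjusted over the list alone, list adjusted p = 0.0144, and adjusted p = 0.252 with an estimated correlation), at adjusted p = 0.0504 without wild-type CMP replicate 1 and 0.0999 without wild-type LSK replicate 1. The other 13 lists did not pass (adjusted p from 0.0686 to 0.941). Their members past the test were 1 late neutrophil, 3 megakaryocyte, 2 mast cell and 3 p53 target genes lower, 3 granulocyte and monocyte regulators higher and 2 lower, 2 lymphoid genes each way and 1 T and NK cell gene each way. The mast cell, B cell, T and NK cell and late neutrophil lists were tested as lower although their median log2 fold changes were 1.85, 1.19, 0.90 and 0.50. The dendritic cell and CEBP family lists were tested as lower with means of 0.21 and 0.13, and the granulocyte and monocyte regulators and the stromal list as higher with medians of −0.19 and −0.01.

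The count of 505 was 101 (36 higher) without wild-type CMP replicate 1, 66 (27 higher) without replicate 6 and 54 (14 higher) without replicate 8. It was 166 (86 higher) without wild-type LSK replicate 1, 880 (504 higher) without replicate 6 and 176 (82 higher) without replicate 8, and DESeq2 called 1609 (728 higher). Hlf, Ly6a, Mpo and Ermap passed in all 6 of these fits.

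The same contrast in enhancer-null animals gave 0 of 11266 genes past the adjusted threshold with edgeR, 780 at an unadjusted p under 0.05, and 205 with DESeq2. Hlf stood at 2.82 ± 4.06 CPM in enhancer-null CMP and 63.2 ± 42.6 in LSK, and Ermap at 233 ± 140 and 3.81 ± 4.84. Mpo stood at 2778 ± 450.5 CPM in enhancer-null CMP and 1751 ± 543 in LSK, and its step from LSK to CMP was smaller than in the wild type in the interaction test (log2 difference −2.96, adjusted p = 0.000732).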

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

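The tests of carry-over into both wild-type gates, of mast cell effector genes in LSK, of the mast cell genes at equal totals and of the wild-type count at equal totals were chosen only after their results had been seen. The genotype effects of 10 named genes differed between CMP and LSK by the interaction test of edgeR, though Lax1, Ltb and Atp8b4 each passed in 1 of 12 fits that left out 1 library, Ctsg in 3 and Slc18a2 in 4. The log2 differences (CMP minus LSK) were 4.20 for Ctla2b, 3.85 for Lax1, 3.70 for Cd63, 3.46 for Slc18a2, 3.41 for Ltb, −6.70 for Tcf7, −5.77 for Csf1r, −5.10 for Ctsg, −4.00 for Irf8 and −3.43 for Atp8b4. Lists whose genotype effects differed between the cell types were primary granule genes (adjusted p = 2.3e-10), granulocyte and monocyte regulators (0.00261), monocyte and macrophage genes (1.78e-07), mast cell and basophil genes (0.00209), stem cell genes (3.05e-05), DNA replication genes (0.0266), immediate early genes (1.63e-13) and respiratory chain genes (0.0399). None of these 8 lists passed with an estimated correlation (adjusted p from 0.0664 to 0.689).

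With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 69 genes in CMP and the highest other split 1, so that 1 of 10 splits gave as many. In LSK the values were 12 and 4, for the interaction 37 and 0, and for the wild-type cell type comparison 505 and 0, again with 1 of 10 splits as large. The LSK split with 4 genes set enhancer-null replicates 1 and 2 and wild-type replicate 1 against the rest, which parts males from females; with sex as a covariate the genotype comparison gave 3 genes. In the enhancer-null cell type comparison 0 genes passed with edgeR in all 10 splits, against 780 at an unadjusted p under 0.05 and 205 with DESeq2 in the real one. Genes called in both CMP and LSK numbered 4, and the highest other split gave 1 (1 of 10 as large). Lists passing camera with the preset correlation numbered 14 against 10 in CMP, 11 against 6 in LSK and 8 against 5 for the interaction, each with 1 of 10 splits as large, and 11 against 11 in the wild type, where 2 of 10 splits gave as many.

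Late neutrophil genes were lower in enhancer-null LSK as a list (0 of 12 past the test over all genes, adjusted p = 1.32e-06, and adjusted p = 0.236 with an estimated correlation), and the lineage depletion that defines the gate would remove mature neutrophils. The tables argued against carry-over into wild-type LSK replicate 1 alone, since without it the median log2 fold change of the 12 tested genes was −3.4 (quartiles −4.05 and −0.969). Carry-over of neutrophil RNA into both wild-type gates stayed open: the median log2 difference between CMP and LSK of the 20 genes tested in the wild type was 0.499 over the groups, but 0.645, 1.3 and −1.39 in replicates 1, 6 and 8, where Ltf stood at 257 against 167, 38.9 against 63.9 and 0 against 30 CPM. Of the list's genes, 2 are also in another list. A loss of late granule transcription in the enhancer-null progenitors themselves stayed open and was not tested.

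Mast cell and basophil genes were higher as a list in both enhancer-null gates (3 of 12 past the test in CMP and 1 of 8 in LSK, with adjusted p = 0.132 and 0.17 with an estimated correlation), and 2 genes of that list are also in another list. Of 8 effector genes, 2 (Mcpt8 and Fcer1a) were above 3 counts in every enhancer-null CMP library and 1 (Mcpt8) in every enhancer-null LSK library. That count could not decide about mature mast cells or basophils, since the 8 genes mix both cell types. Mcpt8 and Ms4a2 were above 3 counts in every wild-type CMP library too. Fcer1a had 170, 179 and 246 counts in enhancer-null CMP against 0, 7 and 0 in wild-type CMP. Mcpt8 had 90, 69 and 98 against 1463, 154 and 14. In enhancer-null CMP Prss34, Cma1, Mcpt4, Tpsb2 and Tpsab1 had 0 counts, so no cells rich in those transcripts were seen there, but Ms4a2 had 336 in replicate 2. In enhancer-null LSK replicate 7, the deepest library, Tpsb2 had 44, Cma1 9 and Fcer1a 187 counts, or 0.873, 0.179 and 3.71 CPM. Fcer1a was at 0 and 3.2 CPM in enhancer-null LSK replicates 1 and 2. Mature mast cells or basophils therefore stayed open. With all libraries thinned to equal totals, a test chosen after its result was seen, the median log2 fold change in CMP was 2.7 over 11 genes (quartiles −1.03 and 4.34). It was 2.63 over 12 before, and no member in both moved by more than 0.865. Progenitors that turn on part of a mast cell programme without Cebpa, and immature mast cell or basophil precursors inside the gates, may both account for the pattern and were not tested.

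Fewer genes differed between CMP and LSK in the enhancer-null than in the wild-type libraries: 0 against 505 with edgeR, 780 against 2463 at an unadjusted p under 0.05, and 205 against 1609 with DESeq2. On 500 genes chosen in 2 wild-type replicates, the median difference in the enhancer-null libraries was 0.358, 0.362 and 0.386 of that in the held-out wild-type replicate. For these genes that argued against a larger spread between the enhancer-null libraries as the whole cause. No set was chosen in the enhancer-null libraries, so differences there in other genes could not be seen. A fit on all 12 libraries, which share an estimate of the spread, gave 37 genes against 482 in the wild type. The enhancer-null count stayed lower at equal totals, a test chosen after its result was seen. There 2471 genes in the wild type and 755 in the enhancer-null libraries were at an unadjusted p under 0.05. On the 500 genes, signed by their wild-type difference from LSK to CMP, the median log2 difference from the held-out wild type was −0.509 to −0.69 in enhancer-null CMP and 0.123 to 0.381 in enhancer-null LSK. A partial block at the step from LSK to CMP, or a changed mix of cells inside the 2 gates, may underlie this. These were not separated here. The number of genes detected at equal totals ran from 10395 to 15961 and averaged 11615 in enhancer-null against 14091 in wild-type CMP. It was not tested as a cause of the smaller count or of the falls in enhancer-null CMP.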

How the results depend on the processing

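Sex as a covariate, thinning to equal totals, identical symbols, all symbols of the LSK files and the interaction without the 2 libraries with most zeros were tests chosen only after the results had been seen. Among 165 named gene results over 2459 alternatives the direction turned in 3, none past the threshold in the main fit. Leaving out 1 library gave Cebpg in LSK −0.573 to 0.0284 (main −0.37; turned without wild-type replicate 6), Uty in LSK −0.0444 to 10.5 (main 1.64; turned without enhancer-null replicate 1) and Siglecf in the wild-type comparison −0.0449 to 1.99 (main 0.52; turned without wild-type LSK replicate 8). No direction turned among the 44 list results past the threshold in the main test, over 444 alternatives. Of the 2 sets, 1876 and 355 kept their side of the threshold, 504 and 89 lost it, and 76 of the former gained it. The cause was not tested unless stated. DESeq2 gave 629 genes in CMP, 268 in LSK, 186 for the interaction, 1609 for the wild-type and 205 for the enhancer-null cell type comparison. On simulated counts 25.9% to 36.3% of its calls were false. Those counts gave each gene the trend's spread, so that share need not hold for the real libraries. Without a filter on low counts the counts were 270, 39, 68 and, for enhancer-null animals, 9. A fit on all 12 libraries gave 232 in CMP, 26 in LSK and 37 in enhancer-null animals. Sex as a covariate gave 31 genes in CMP and 3 in LSK, with 1 degree of freedom fewer. Without the 2 libraries with most zeros the interaction gave 24. Leaving out 1 library gave 7 to 92 genes in CMP, 1 to 21 in LSK, 12 to 107 for the interaction, 54 to 880 in the wild type and 0 in the enhancer-null comparison; lists ranged over 12 to 17, 9 to 13, 7 to 12 and 10 to 12. Some lists outside the 44 passed there, such as late neutrophil genes in CMP (4 of 6 fits) and G2 and mitosis genes in the interaction (6 of 12). An estimated correlation gave 0, 0, 0 and 1 lists. With fry 9, 2 and 4 lists passed in the first 3 comparisons, the 9 including the granulocyte and monocyte regulators (adjusted p = 0.0418), which did not pass in the main test. Shared genotype calls numbered 12 at an adjusted p under 0.1 and 73 with DESeq2. The replicate block gave 7 genes for the interaction, 132 in the wild type and 0 in enhancer-null animals. Same-numbered CMP and LSK libraries correlated by −0.112 to 0.145 in their deviations from the group means, and 2 of 6 correlated best with their own number. The numbers were therefore not taken to pair the libraries, although the sexes matched and shared animals were not excluded. RLE scaling, the stricter filter, no robust prior, thinning, identical symbols and all LSK symbols moved no gene count by more than 1.5 times in the comparisons they were run on. Low counts limit how closely the fall of Cebpa can be sized, since it had 0 to 15 counts per enhancer-null library. The same limit holds for the rise of Tcf7 in LSK, whose wild-type level lay near the floor.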

Other observations

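The tests on genes near Cebpa, and the list tests in enhancer-null animals, were chosen after results had been seen. Erythroid genes separated CMP from LSK in enhancer-null animals too. As a list, 32 tested genes were higher in enhancer-null CMP (median log2 fold change 3.56, camera adjusted p = 1.63e-44, and adjusted p = 0.0976 with an estimated correlation), with 0 members past the test over all genes and 24 adjusted over the list alone. Interferon response genes were lower (44 genes, median −0.70, adjusted p = 1.12e-07, and adjusted p = 0.0613 with an estimated correlation), with 0 members past the test over all genes and 2 lower adjusted over the list alone. Stem cell genes were lower (36 genes, median −0.71, adjusted p = 3.63e-06, and adjusted p = 0.0697 with an estimated correlation), as were dendritic cell genes (15 genes, median −1.08, adjusted p = 1.78e-05, and adjusted p = 0.0697 with an estimated correlation). Mast cell and basophil genes were higher (10 genes, median 0.99, adjusted p = 0.000106, and adjusted p = 0.211 with an estimated correlation). There were 7 stem cell genes lower and 1 higher, 3 dendritic cell genes lower and 4 mast cell genes higher adjusted over the list alone, and 0 members of these 3 lists passed over all genes. Of the 25 lists tested, 11 passed with the preset correlation and 0 with an estimated one. Monocyte and primary granule genes did not pass (adjusted p = 0.0764 and 0.103). Both lists rose from LSK to CMP in the wild type with the preset correlation, but not with an estimated one (adjusted p = 0.141 and 0.233). Their differences in genotype effect are those of the interaction test (adjusted p = 1.78e-07 and 2.3e-10, and adjusted p = 0.102 and 0.0664 with an estimated correlation). Pdgfrb, a receptor of stromal cells, stood at 152 ± 47.9 against 31.5 ± 10.8 CPM in CMP (adjusted p = 0.0542) and at 213 ± 68.4 against 25.9 ± 15.2 CPM in LSK (adjusted p = 0.131).

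One hypothesis was that deleting the enhancer changes other genes of the region. Of the genes within 1 Mb of Cebpa, 16 were tested in CMP and 15 in LSK, and 0 passed with edgeR (lowest adjusted p 0.502 and 0.614) or with DESeq2. At an unadjusted p under 0.05 there were 0 in CMP and 1 in LSK. Their median log2 fold changes were −0.278 and 0.141. Changes too small for 3 libraries a group could be missed, so an effect on neighbours stays open.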
